A study of Mus musculus with 6 samples.

How the data were processed

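The data are gene expression profiles of 6 RNA-seq libraries from mouse lung alveolar organoid cells, 2 in each of 3 culture conditions. The libraries came from polyA RNA, purified with RNeasy columns and prepared with the NEB Ultra II chemistry, per the labels' protocols. The cell lines SN3593 and SN3595 each contributed 1 library to each condition. Groups were taken from the treatment labels. Nothing beyond the line names says that the lines came from separate animals, so p-values measure the spread between these 2 lines and their cultures, part of which may be technical.

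The authors deposited a table of expected counts per gene, which are estimated read numbers that need not be whole. The submitters' processing notes name RSEM 1.3.1, Bowtie 1.2.3 and the genome build mm9. The annotation and the options of those tools are not given in the sources used here. The genome at hand was another build, so no coordinates are given and genes are identified by the symbol in the table. The table had 23224 genes. Some symbols were older ones, such as Ctgf, Chi3l1 and Pkm2, and list members were matched through both forms. Of 515 list entries, 2 (Pxdc1 and Hmgcs1) had no row in the table used. A further 25 symbols had been turned into dates, of which 19 passed the filter; they stayed in the tests and are not named. Whether strand was used in counting is not given in the sources used here, so overlapping and antisense genes cannot be told apart. Expected counts divide reads that match several genes by a model, so values of close relatives, such as Lyz1 and Lyz2, Hspa1a and Hspa1b or the actin genes, are uncertain individually.

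Total expected counts were 34569063 and 36137242 in the 3D FNHCS libraries of SN3593 and SN3595, 33634368 and 40104737 in 2D FNHCS, and 38033723 and 43334665 in 2D FBS. A count of 0 was given a floor of 3 counts per library, which corresponds to 0.0704 to 0.0864 CPM, the count scaled to the library total. Floors and counting intervals (exact, at the 95% level) cover counting error only. Libraries of the same condition had a Pearson correlation of log CPM across genes of 0.974 in 3D FNHCS, 0.965 in 2D FNHCS and 0.979 in 2D FBS. A chi-square test of their counts gave 175, 189 and 154 per degree of freedom, so each pair differed by far more than sampling noise and all libraries were kept as separate samples.

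Expected counts were rounded to whole numbers. The main test was edgeR 4.0.16 in R 4.3.3, with TMM scaling, its default filter on low counts, and the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. All 6 libraries entered a single fit with a term for each group, because 2 libraries per group estimate the spread poorly alone, which left 3 residual degrees of freedom. The filter kept 14416 genes and left out 8808. The 3 contrasts tested were 2D FNHCS against 3D FNHCS, 2D FBS against 2D FNHCS, and 2D FBS against 3D FNHCS. The lines were compared in a fit with group as a further term. Log2 fold changes are given with an approximate standard error (SE). It is the absolute log2 fold change divided by the square root of the F statistic of the quasi-likelihood test. CPM are TMM-scaled means with their standard deviation (SD) over 2 libraries.

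Genes are called where the adjusted p was below 0.05. Named genes follow a rule fixed before the data were examined, as were the groups, tests, gene lists and alternatives. The rule takes Sftpc, Ager, Hopx, Pdpn and Nkx2-1 in each comparison of groups. It adds the 5 largest rises and the 5 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between libraries, predicted genes excluded. It further adds the 4 called AT2 and the 4 called AT1 markers with the lowest adjusted p, and the 2 called members with the lowest adjusted p of the 8 other lists with the lowest p among called lists. For the lines it takes Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, and the 3 largest changes each way. Members of a list that were not called may be named with their values. A fold against a group with 0 counts is given as a lower bound at the floor. The fixed rule asked for a bound wherever every library of a group had at most 3 counts. Departing from it, the ratio with its counting interval is given against a group with 1 to 3 counts.

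The 28 gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated per list and fry were alternatives. Fry tests whether the genes of a list move one way on balance and does not compare a list with other genes. The lists cover alveolar type 2 (AT2) and type 1 (AT1) markers, an alveolar transitional state, YAP and TAZ targets, the actin cytoskeleton, basement membrane and matrix, mesenchymal transition, epithelial identity, targets of TGF-beta, BMP, Wnt and FGF or MAPK signalling, the cell cycle, fatty acid and cholesterol synthesis, interferon, NF-kB and MHC class II genes, p53 targets, endoplasmic reticulum (ER) and amino acid stress, hypoxia and glycolysis, and immediate early genes. They also cover markers of airway, gastrointestinal, fibroblast, leukocyte, endothelial and mesothelial cells. List medians were also computed with genes at 0 in a group set to their bound, which changed none of the medians.

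The same lines occur in every condition, so the line pairs the libraries. Deviations from the group means correlated between conditions, with r of 0.42 for 3D FNHCS with 2D FNHCS, 0.24 for 3D FNHCS with 2D FBS and 0.38 for 2D FNHCS with 2D FBS. The fit with line as a block, which left 2 residual degrees of freedom, was an alternative. Others were the RLE, upper-quartile and library-size scalings, no filter, a filter of 1 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, a fit of only the libraries compared, an added 2-fold minimum, and leaving out each library in turn.

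The procedure was tested on simulated counts for the same 14416 genes, with 2-, 4- and 8-fold changes planted in 67, 67 and 66 genes. In 2D FNHCS against 3D FNHCS it recovered 5.97%, 58.2% and 74.2% of them, with 7 false calls among 99. For 2D FBS against 2D FNHCS the shares were 2.99%, 67.2% and 84.8%, with 7 false calls among 110. For 2D FBS against 3D FNHCS they were 4.48%, 58.2% and 80.3%, with 13 false calls among 108. The comparison of lines recovered 10.4%, 68.7% and 90.9%, with 5 false calls among 118. Far more genes were called in the real comparisons of conditions, where the adjustment is then less strict, so these shares need not carry over. A planted list of 20 genes changed 2-fold was called in 2D FNHCS against 3D FNHCS at the preset correlation, with adjusted p = 1.21e-22, and with an estimated correlation, with adjusted p = 0.0443. Simulated genes were drawn independently of each other, so this list cannot show how either test treats lists whose genes move together.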

Results

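Alveolar organoid cells grown from mouse lung were profiled in 3 culture conditions after 7 days. The genotype is Sftpc-eGFP, and the cells belong to a platform built on alveolar type 2 (AT2) cells, which secrete surfactant and give rise to the flat alveolar type 1 (AT1) cells of the gas exchange surface. In 3D FNHCS the cells stayed in drops of matrigel with a medium called FNHCS. In 2D FNHCS they grew flat in the same medium. In 2D FBS they grew flat in Ad-DMEM F/12 with 10% fetal bovine serum. Sample titles mark the 3D libraries as type II, the 2D FNHCS libraries as AT2 and AT1, and the 2D FBS libraries as type I. The series design mentions eGFP-positive and eGFP-negative cells. Whether these libraries came from cells sorted on eGFP is not given in the sources used here, and such a sort would bear on the levels of Sftpc and other AT2 markers. Each condition had 1 library of line SN3593 and 1 of line SN3595. Total expected counts per library ranged from 33634368 to 43334665.

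The first principal component held 67.3% of the variance and placed the conditions in the order 3D FNHCS, 2D FNHCS, 2D FBS. The second held 16.1% and set 2D FNHCS apart from both others, and the third held 9.96% and separated the lines within each condition. Sftpc, which encodes surfactant protein C, alone took 3.37% and 4.0% of counts in the 3D libraries, 5.91% and 4.36% in 2D FNHCS, and 0.0401% and 0.0241% in 2D FBS (SN3593 and SN3595). The ribosomal precursor Rn45s took 1.60% and 1.03% in 3D FNHCS, 0.50% and 0.679% in 2D FNHCS, and 0.371% and 0.259% in 2D FBS. Scaling by library size alone moved the median log2 fold change of all genes to 0.19 in 2D FNHCS against 3D FNHCS (0.03 with TMM) and to -0.33 in 2D FBS against 2D FNHCS (-0.06 with TMM). In 2D FBS against 3D FNHCS the median was -0.03 with TMM and -0.19 with upper-quartile factors.

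**Figure D1:**
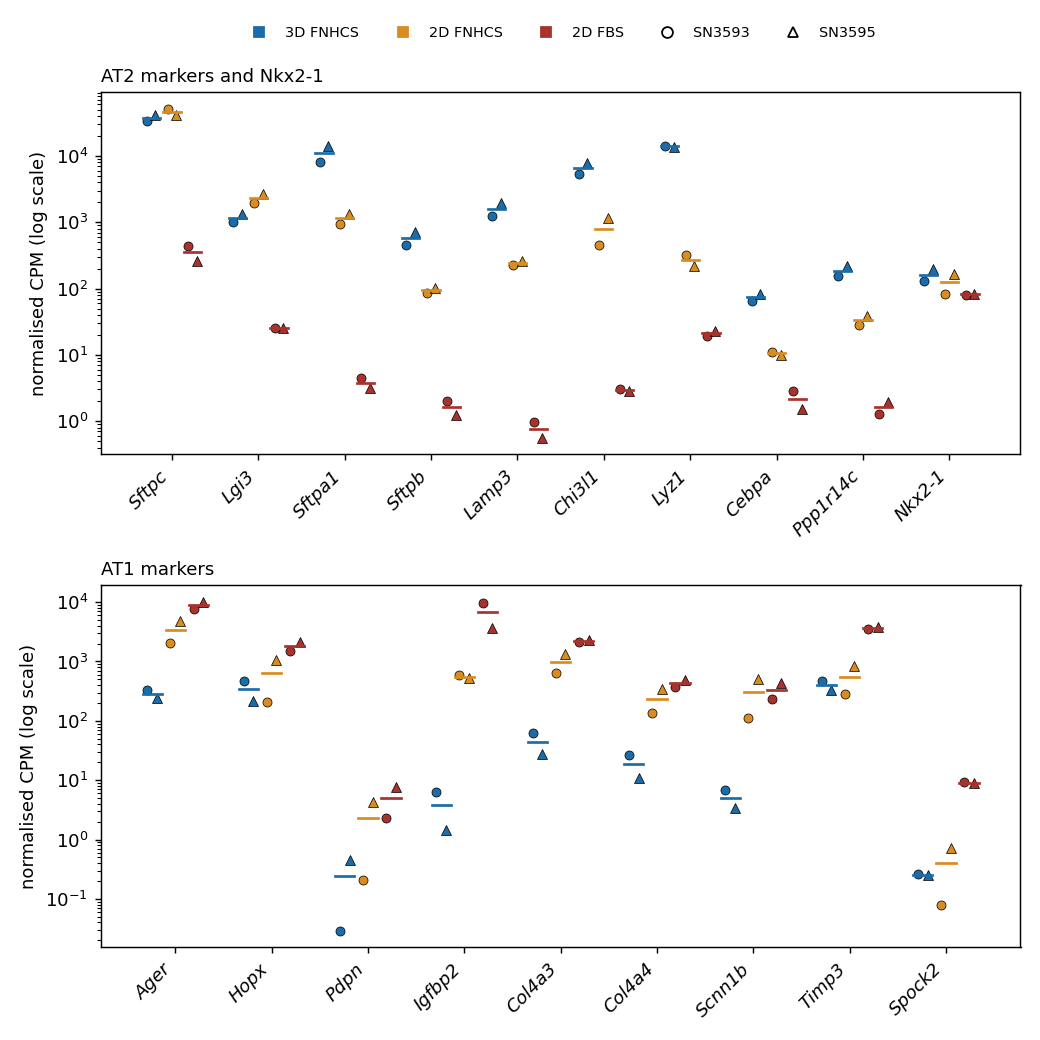
Normalised expression in library-scaled counts (CPM, log scale) of AT2 markers with Nkx2-1 (top) and AT1 markers (bottom) in each library, with colour for condition, symbol shape for line and a bar for the mean of 2 libraries. Sftpc stood at 33500 CPM or more in the 3D FNHCS and 2D FNHCS libraries and at 438 and 264 CPM in 2D FBS, while Ager rose from 326 and 243 CPM in 3D FNHCS to 7535 and 10120 CPM in 2D FBS.

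The first comparison asked what flat culture changes at constant medium. Sftpc stood at 37260 ± 5312 CPM (SD, n = 2) in 3D FNHCS and at 46210 ± 7388 CPM in 2D FNHCS and was not called (log2 fold change 0.31 ± 0.419 SE, adjusted p = 0.626, edgeR). Other AT2 genes fell: the lysozyme gene Lyz1, whose reads can be shared with Lyz2, went from 13960 ± 359 to 270 ± 74.2 CPM (-5.69 ± 0.381, adjusted p = 0.00291), and the alarmin gene Il33 fell by 6.38 ± 0.697 on the log2 scale. The AT1 gene Ager, for the receptor for advanced glycation end-products, rose from 285 ± 58.5 to 3434 ± 1911 CPM (3.59 ± 0.501, adjusted p = 0.00993). Glycolysis and hypoxia-induced genes fell together, among them Pdk1, a kinase that inhibits pyruvate dehydrogenase (-3.40 ± 0.198). In all, 2652 of 14416 genes (18.4%) were called, 1244 higher and 1408 lower in 2D FNHCS.

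Of the 26 AT2 markers tested, 12 fell and 14 were not called (14 fell and 1 rose adjusted over the list alone). The list test gave adjusted p = 3.4e-09, or adjusted p = 0.219 with an estimated correlation. Among those that fell were the transcription factor gene Cebpa (-2.81 ± 0.313) and the phosphatase inhibitor gene Ppp1r14c (-2.49 ± 0.302). Lgi3 (1.0 ± 0.272) and the lung transcription factor gene Nkx2-1 (-0.38 ± 0.356, adjusted p = 0.477) were not called. Of 25 AT1 markers, 7 rose and 18 were not called (16 rose adjusted over the list alone, and 12 with line as a block). That list gave adjusted p = 4.99e-07, or adjusted p = 0.519 with an estimated correlation. Igfbp2, for a binding protein of insulin-like growth factors, rose by 7.17 ± 0.936, the sodium channel gene Scnn1b by 5.92 ± 0.891 and the basement membrane collagen gene Col4a3 by 4.46 ± 0.56. Hopx (0.89 ± 0.76, adjusted p = 0.438) moved by -1.19 in SN3593 and by 2.33 in SN3595 and was not called. Pdpn rested on 17 counts in 3D FNHCS (3.23 ± 1.59, adjusted p = 0.199, or adjusted p = 0.047 with line as a block). Ager was not called without the 3D library of SN3593 (adjusted p = 0.0573) or of SN3595 (adjusted p = 0.057), nor was Scnn1b (adjusted p = 0.0603 and 0.065).

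In the hypoxia and glycolysis list, 15 of 17 genes fell (16 adjusted over the list alone), with a median log2 fold change of -2.96. The list gave adjusted p = 4.55e-28, or adjusted p = 0.219 with an estimated correlation. Beside Pdk1, the mitophagy gene Bnip3 fell by 3.63 ± 0.243. Egln3, a prolyl hydroxylase that marks hypoxia-inducible factors, went from 474 ± 98.4 to 0.783 ± 0.577 CPM (-9.25 ± 0.925, adjusted p = 0.00485). Slc16a3, which encodes a lactate exporter, went from 235 ± 119 to 0.922 ± 0.023 CPM (-7.99 ± 0.57). Eno1 (-1.08 ± 0.294) and Pfkfb3 (-0.08 ± 0.424) were not called. Immediate early genes, which also respond to dissociation and handling, were lower too: 7 of 14 fell (10 fell and 1 rose adjusted over the list alone, 11 and 1 with line as a block). Their list gave adjusted p = 3.91e-11, or adjusted p = 0.219 with an estimated correlation, with Fosb at -5.91 ± 0.327 and Socs3 at -3.01 ± 0.207.

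The other named changes were of several kinds. The largest rises were those of Popdc3, a cAMP-binding membrane protein with a ratio of 470 (counting interval 130 to 3880, from 2 counts in 3D FNHCS), Ltbp2, a latent TGF-beta binding protein (8.69 ± 0.478), the small GTPase gene Rasl10b (7.34 ± 0.612), Igfbp2 and the annexin gene Anxa8 (7.05 ± 1.27). Anxa8 was not called without either 3D library (adjusted p = 0.0959 for each) or by limma-voom (adjusted p = 0.116). The largest falls were those of Tmem213, with a ratio of 2950 (530 to 117000, from 1 count in 2D FNHCS), Egln3, the neuropeptide Y receptor gene Npy2r (-9.04 ± 0.579), Slc16a3 and the peptide ligand gene Apln (-7.77 ± 0.797).

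At the preset correlation, several signalling and growth lists were lower in 2D FNHCS. TGF-beta targets were not called and YAP and TAZ targets were higher. By fry, the BMP, FGF and MAPK, and fatty acid lists were called (adjusted p between 0.00986 and 0.0326). The Wnt, cell cycle and NF-kB lists were not called by fry (adjusted p between 0.113 and 0.151). Of 12 BMP targets, 6 fell and 1 rose (8 and 1 adjusted over the list alone), with Id2 at -4.35 ± 0.201 and Id1 at -4.00 ± 0.211, both inhibitors of DNA binding. The list gave adjusted p = 3.99e-06, or adjusted p = 0.328 with an estimated correlation. Of 18 FGF and MAPK targets, 6 fell (9 adjusted over the list alone), including the feedback inhibitor genes Spry4 (-2.97 ± 0.284) and Dusp5 (-3.57 ± 0.401). Their list gave adjusted p = 0.000111, or adjusted p = 0.219 with an estimated correlation. It shares Egr1 with the immediate early genes, of which 7 of 14 fell in this comparison, and handling was not separated from signalling here. Of 13 Wnt targets, 3 fell over all genes and adjusted over the list alone (list adjusted p = 0.0102, or adjusted p = 0.519 with an estimated correlation). The Wnt call was lost without the 3D library of SN3593 (adjusted p = 0.112) or the 2D FNHCS library of SN3595 (adjusted p = 0.173). Of 29 cell cycle genes, 8 fell (16 adjusted over the list alone, 14 with line as a block), with the mitotic kinase gene Cdk1 at -1.92 ± 0.224 and the centromere histone gene Cenpa at -2.33 ± 0.316. That list gave adjusted p = 0.000111, or adjusted p = 0.519 with an estimated correlation. Of 20 fatty acid synthesis genes, 8 fell (13 adjusted over the list alone), with the acyltransferase gene Gpam at -2.67 ± 0.246 and the elongase gene Elovl6 at -3.09 ± 0.36. It gave adjusted p = 9.56e-06, or adjusted p = 0.308 with an estimated correlation. Of 17 NF-kB and chemokine genes, 6 fell (7 fell and 1 rose adjusted over the list alone; list adjusted p = 0.000885, or adjusted p = 0.519 with an estimated correlation).

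Adhesion, matrix and stress lists were higher at the preset correlation. By fry, the transitional state list was called (adjusted p = 0.0123). The actin, matrix, YAP and TAZ, mesenchymal, p53 and ER stress lists were not called by fry (adjusted p between 0.0536 and 0.153). Of 25 actin cytoskeleton and focal adhesion genes, 7 rose (8 adjusted over the list alone, 12 with line as a block), with the myosin light chain gene Myl9 at 5.80 ± 0.666 and the adhesion gene Zyx at 1.2 ± 0.206. The list gave adjusted p = 0.000111, or adjusted p = 0.519 with an estimated correlation. Zyx was not called without the 3D library of SN3593 (adjusted p = 0.0964) or of SN3595 (adjusted p = 0.0733). Of 19 basement membrane and matrix genes, 6 rose and 1 fell (10 and 1 adjusted over the list alone; list adjusted p = 0.000111, or adjusted p = 0.338 with an estimated correlation). The fibrillar collagen gene Col5a2 had 0 counts in 3D FNHCS and was at least 25.2-fold higher in 2D FNHCS, and the basement membrane collagen gene Col4a1 rose by 2.54 ± 0.345. Of 20 YAP and TAZ targets, 8 rose and 2 fell (10 and 2 adjusted over the list alone; list adjusted p = 0.00345, or adjusted p = 0.519 with an estimated correlation). Of 21 transitional state genes, 7 rose and 3 fell (8 and 3 adjusted over the list alone; list adjusted p = 0.00268, or adjusted p = 0.219 with an estimated correlation). Of 13 mesenchymal transition genes, 5 rose over all genes and adjusted over the list alone (list adjusted p = 0.00112, or adjusted p = 0.503 with an estimated correlation). That list shares Acta2 with the actin list and Fn1 and Sparc with the matrix list, so in each comparison it is not fully separate from them. Before TMM scaling, Snai1, Zeb2, Cdh2 and Zeb1 reached at most 0.342, 0.595, 0.803 and 3.58 CPM and Vim 98.9 CPM. Snai2, Twist1 and Twist2 did not pass the filter. Of 19 p53 targets, 5 rose (8 rose and 1 fell adjusted over the list alone, 10 and 1 with line as a block; list adjusted p = 0.00268, or adjusted p = 0.338 with an estimated correlation). Of 15 ER and amino acid stress genes, 4 rose (5 adjusted over the list alone), with list adjusted p = 0.0433, or adjusted p = 0.519 with an estimated correlation. The ER stress call was lost with line as a block (adjusted p = 0.0623), and without the 3D library of SN3593 (adjusted p = 0.112), the 2D FNHCS library of SN3593 (adjusted p = 0.344) or the 2D FBS library of SN3595 (adjusted p = 0.0507).

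The remaining 11 lists were not called. Epithelial identity genes split into 3 that rose and 2 that fell among 21 (4 and 2 adjusted over the list alone; list adjusted p = 0.657), and TGF-beta targets into 3 and 3 among 15 (4 and 4 adjusted over the list alone; list adjusted p = 0.863), with a median of -0.24 and a mean of 0.25. Cholesterol synthesis had 1 of 22 genes that rose, also adjusted over the list alone (list adjusted p = 0.657), and was called lower without the 2D FNHCS library of SN3595 (adjusted p = 0.00131). None of 23 interferon-stimulated genes was called by edgeR over all genes or adjusted over the list alone (1 at an unadjusted p below 0.05, 1 by DESeq2 and 0 by limma-voom; list adjusted p = 0.863), yet that list was called higher without the 3D library of SN3595 (adjusted p = 0.0171) and lower without the 2D FNHCS library of SN3595 (adjusted p = 0.0116). None of 7 MHC class II genes was called by edgeR over all genes or adjusted over the list alone (1 at an unadjusted p below 0.05, 1 by DESeq2 and 1 by limma-voom; list adjusted p = 0.154), and that list was called lower with line as a block (adjusted p = 0.0228), without the filter (adjusted p = 0.0464) and without the 2D FNHCS library of SN3593 (adjusted p = 0.000266). With line as a block, 2 interferon-stimulated, 2 cholesterol synthesis, 2 airway and 1 fibroblast gene rose, and 4 cholesterol synthesis, 3 MHC class II, 5 TGF-beta and 1 fibroblast gene fell. Markers of other cell types were sparse: 9 of 18 airway, 8 of 18 gastrointestinal, 4 of 16 fibroblast, 3 of 13 leukocyte, 2 of 11 endothelial and 3 of 7 mesothelial genes passed the filter. Of these, 1 airway and 1 gastrointestinal gene rose, and 2 airway, 2 gastrointestinal, 1 leukocyte and 1 endothelial gene fell. Adjusted over the list alone, 1 airway, 1 gastrointestinal, 1 leukocyte and 1 endothelial gene rose, and 2 airway, 3 gastrointestinal, 1 leukocyte and 1 endothelial gene fell. The fibroblast and mesothelial genes were not called by edgeR. At an unadjusted p below 0.05, 2 fibroblast genes and 1 mesothelial gene passed, of which DESeq2 called 1 and limma-voom 0. Their list tests gave adjusted p between 0.431 and 0.863.

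The count of called genes depended on single libraries in this comparison. It was 565 without the 3D library of SN3593 (184 higher, 381 lower), 802 without that of SN3595 (298 higher, 504 lower) and 1283 without the 2D FNHCS library of SN3595 (648 higher, 635 lower). Without the 2D FNHCS library of SN3593 there were 1073 higher and 796 lower, so the share that was higher went from 46.9% to between 32.6% and 57.4%. Without the 2D FBS library of SN3593 or SN3595, 808 and 784 were higher and 998 and 1026 lower. The count was 4181 with line as a block (2046 higher, 2135 lower), which kept 2641 of the 2652. Libraries did not overlap between the conditions for 9185 genes (63.7%), where chance gives 33.3%, and with library size scaling 1885 were called higher and 1137 lower.

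**Figure D2:**
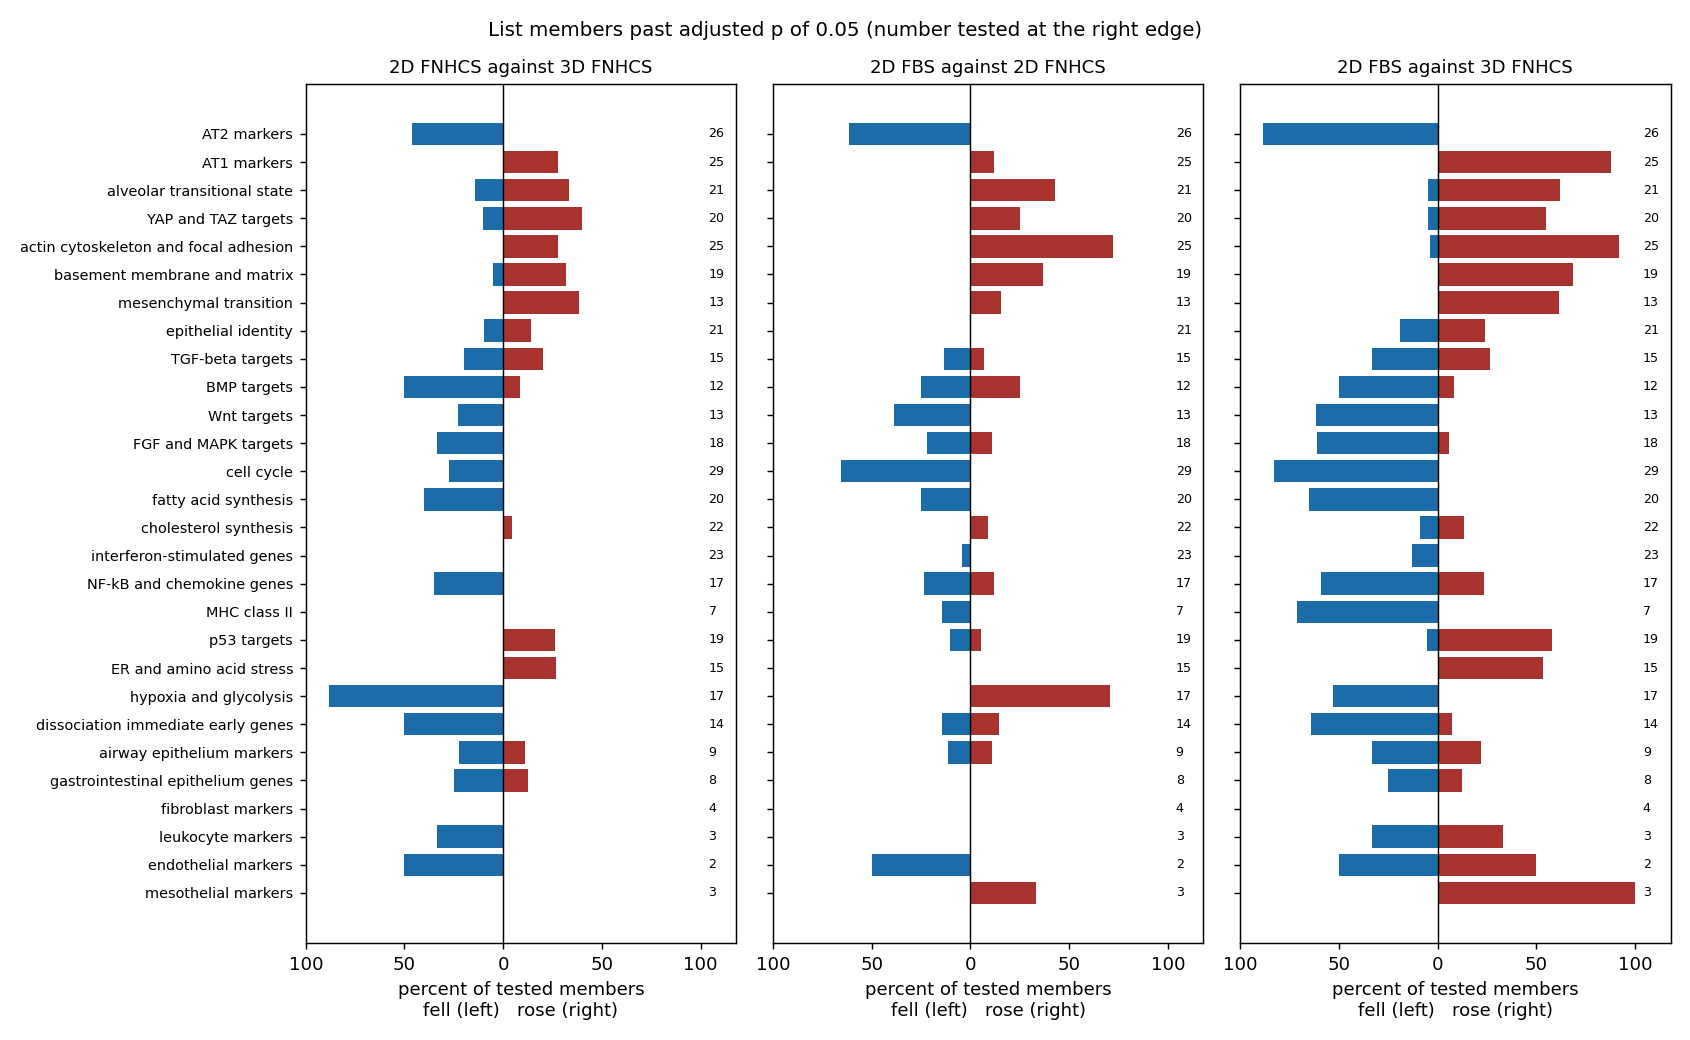
Percent of the tested members of each of the 28 gene lists that rose (red, to the right) or fell (blue, to the left) at an adjusted p below 0.05 in the 3 comparisons of conditions, with the number of members tested at the right edge of each panel. In 2D FNHCS against 3D FNHCS, 15 of 17 hypoxia and glycolysis genes fell, and in 2D FBS against 2D FNHCS 12 of 17 rose.

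The second comparison asked what replacing FNHCS with the serum medium changes in flat culture. Loss of FNHCS and gain of serum came together and cannot be told apart. Sftpc fell from 46210 ± 7388 to 351 ± 123 CPM (SD, n = 2; log2 fold change -7.04 ± 0.545 SE, adjusted p = 0.00613, edgeR). The lamellar body gene Lamp3 fell by 8.31 ± 0.458 and the surfactant protein A gene Sftpa1 fell by 8.24 ± 0.534. Of 25 actin cytoskeleton and focal adhesion genes 18 rose, with Myl9 going from 8.14 ± 0.356 to 651 ± 416 CPM (6.32 ± 0.572) and the actin-binding protein gene Tagln from 1.57 CPM to 78.0 CPM (5.63 ± 0.43). Of 17 hypoxia and glycolysis genes 12 rose, with Pdk1 at 2.22 ± 0.189. In all, 1531 genes (10.6% of those tested) were called, 843 higher and 688 lower in 2D FBS.

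Of 26 AT2 markers, 16 fell and 10 were not called (21 fell adjusted over the list alone), with a median of -4.03. The list gave adjusted p = 2.03e-44, or adjusted p = 0.0965 with an estimated correlation. Surfactant protein B gene Sftpb fell by 5.84 ± 0.386 and Lgi3, a secreted protein gene, by 6.50 ± 0.342. Nkx2-1 was not called (-0.60 ± 0.357, adjusted p = 0.304). Of 25 AT1 markers, 3 rose and 22 were not called, over all genes and adjusted over the list alone, with a median of 1.12. Their list gave adjusted p = 1.01e-05, or adjusted p = 0.625 with an estimated correlation. The 3 were the proteoglycan gene Spock2 (4.46 ± 0.858), the metalloproteinase inhibitor gene Timp3 (2.70 ± 0.54) and Igfbp2 (3.58 ± 0.786). Ager (1.36 ± 0.46, adjusted p = 0.113), Hopx (1.5 ± 0.771, adjusted p = 0.249) and Pdpn (1.12 ± 1.37, adjusted p = 0.609) were not called. Ager was called by DESeq2 (adjusted p = 0.00937), and Ager and Hopx were called without the 2D FNHCS library of SN3595 (adjusted p = 0.0422 and 0.0398), and Sftpc was not without the 2D FBS library of SN3593 (adjusted p = 0.0577). Without that library or the 2D FBS library of SN3595, Spock2 (adjusted p = 0.124 and 0.0977), Timp3 (adjusted p = 0.124 and 0.107) and Igfbp2 (adjusted p = 0.157 and 0.0709) were not called. Spock2 and Timp3 were not called either without the 3D library of SN3593 (adjusted p = 0.0567 and 0.0578) or of SN3595 (adjusted p = 0.0571 for each). Timp3 (adjusted p = 0.0508) and Igfbp2 (adjusted p = 0.132) also lost their calls without the 2D FNHCS library of SN3593, and Igfbp2 without that of SN3595 (adjusted p = 0.105).

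The 5 largest rises were those of Npy6r, a neuropeptide Y receptor gene with 0 counts in 2D FNHCS that was at least 147-fold higher, the smooth muscle myosin gene Myh11, the endosialin gene Cd248, the atrial myosin light chain gene Myl7 and the surface antigen gene Psca. Ratios from 1 to 3 counts in 2D FNHCS were 1740 for Myh11 (counting interval 594 to 8420), 1210 for Cd248 (217 to 47800) and 993 for Myl7 (275 to 8200), and Psca had a log2 fold change of 9.64 ± 1.41. The 5 largest falls were those of the acute phase gene Saa3 (ratio 877, 157 to 34600, from 1 count in 2D FBS), Lamp3, Sftpa1, the anion exchanger gene Slc26a4 (-8.13 ± 0.828) and the chitinase-like gene Chi3l1 (-8.07 ± 0.632). Without the 2D FBS library of SN3593, calls were lost for Npy6r (adjusted p = 0.0772), Myl7 (adjusted p = 0.0659), Psca (adjusted p = 0.0611), Saa3 (adjusted p = 0.182) and Chi3l1 (adjusted p = 0.0603). Myl7 and Psca were not called without the 2D FNHCS library of SN3593 (adjusted p = 0.0619 and 0.0622), nor Saa3 without the 2D FBS library of SN3595 (adjusted p = 0.181) or the 3D library of SN3593 or SN3595 (adjusted p = 0.0591 and 0.058). By limma-voom, Myh11, Myl7, Psca and Saa3 had adjusted p between 0.0686 and 0.205, and by DESeq2 Npy6r had adjusted p = 0.0752.

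Of 25 actin cytoskeleton and focal adhesion genes, 18 rose (22 rose and 1 fell adjusted over the list alone; list adjusted p = 3.73e-18, or adjusted p = 0.354 with an estimated correlation). The list holds Acta2, Tagln, Cnn1 and Myl9, which smooth muscle cells also express, and the presence of such cells in 2D FBS was not excluded. Of 17 hypoxia and glycolysis genes, 12 rose (14 adjusted over the list alone; list adjusted p = 1.22e-17, or adjusted p = 0.318 with an estimated correlation), with the collagen hydroxylase gene P4ha1 at 2.08 ± 0.201. Immediate early genes did not follow, with 2 of 14 that rose and 2 that fell (3 and 3 adjusted over the list alone; list adjusted p = 0.703). Of 21 transitional state genes, 9 rose (13 rose and 1 fell adjusted over the list alone; list adjusted p = 6.79e-09, or adjusted p = 0.0965 with an estimated correlation). Among them were Plaur, the urokinase receptor gene (4.55 ± 0.214), and the keratin gene Krt19 (1.90 ± 0.24). Of 20 YAP and TAZ targets, 5 rose (8 adjusted over the list alone), with the tissue factor gene F3 at 3.80 ± 0.294 and Ankrd1 at 3.88 ± 0.468. Their list gave adjusted p = 3.18e-07, or adjusted p = 0.401 with an estimated correlation. Of 19 basement membrane and matrix genes, 7 rose over all genes and adjusted over the list alone, with Col5a2 at 3.75 ± 0.426 and the collagen crosslinking enzyme gene Lox at 5.57 ± 0.82. That list gave adjusted p = 0.000231, or adjusted p = 0.401 with an estimated correlation. Without the 2D FBS library of SN3593, calls were lost for P4ha1 (adjusted p = 0.0525), Krt19 (adjusted p = 0.0738), Ankrd1 (adjusted p = 0.0659), Col5a2 (adjusted p = 0.0805) and Lox (adjusted p = 0.0772). Col5a2 and Lox were not called without the 2D FBS library of SN3595 (adjusted p = 0.0505 and 0.0516), nor Lox without the 2D FNHCS library of SN3593 (adjusted p = 0.0594).

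Of 13 mesenchymal transition genes, 2 rose (6 adjusted over the list alone; list adjusted p = 0.0357, or adjusted p = 0.625 with an estimated correlation), a call lost without the 2D FNHCS library of SN3595 (adjusted p = 0.189) or the 2D FBS library of SN3593 (adjusted p = 0.08). Of 22 cholesterol synthesis genes, 2 rose (3 adjusted over the list alone, and 6 with line as a block, where 1 fell), Hsd17b7 by 1.98 ± 0.286 and Pmvk by 1.28 ± 0.238. The list gave adjusted p = 0.00603, or adjusted p = 0.745 with an estimated correlation, and was not called without the 2D FNHCS library of SN3593 (adjusted p = 0.422) or the 2D FBS library of SN3595 (adjusted p = 0.184). Both genes lost their calls without the 2D FBS library of SN3593 (adjusted p = 0.0676 and 0.0986) or of SN3595 (adjusted p = 0.0619 and 0.115). Pmvk was also not called without the 2D FNHCS library of SN3593 (adjusted p = 0.0865) or the 3D library of SN3593 or SN3595 (adjusted p = 0.053 and 0.0544). Of 3 mesothelial markers, 1 rose (2 adjusted over the list alone and with line as a block; list adjusted p = 0.0222, or adjusted p = 0.378 with an estimated correlation). Its uncalled members were Msln (157 CPM in 2D FNHCS and 1347 CPM in 2D FBS) and Gpm6a (0.112 and 4.09 CPM).

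Cell cycle genes were lower: 19 of 29 fell (25 adjusted over the list alone), with Cdk1 at -4.47 ± 0.269 and Cenpa at -3.56 ± 0.36. DESeq2 called 24 of the 29 and limma-voom 7. That list gave adjusted p = 1.34e-18, or adjusted p = 0.378 with an estimated correlation. Of 13 Wnt targets, 5 fell (7 fell and 1 rose adjusted over the list alone; list adjusted p = 0.000156, or adjusted p = 0.401 with an estimated correlation), including the transcription factor gene Sp5 (-1.55 ± 0.175) and the ubiquitin ligase gene Rnf43 (-1.32 ± 0.208). Of 20 fatty acid synthesis genes, 5 fell over all genes and adjusted over the list alone (list adjusted p = 0.013, or adjusted p = 0.401 with an estimated correlation). Of 7 MHC class II genes, 1 fell (4 adjusted over the list alone and with line as a block; list adjusted p = 0.00603, or adjusted p = 0.625 with an estimated correlation), and the list was not called without the 2D FBS library of SN3595 (adjusted p = 0.0621). Cenpa (adjusted p = 0.0659), Sp5 (adjusted p = 0.0766) and Rnf43 (adjusted p = 0.115) were not called without the 2D FBS library of SN3593. Rnf43 was not called either without the 2D FBS library of SN3595 (adjusted p = 0.0672) or the 2D FNHCS library of SN3593 (adjusted p = 0.0622).

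Apart from the immediate early genes, 13 lists were not called. BMP targets split into 3 that rose and 3 that fell among 12 (3 and 4 adjusted over the list alone), FGF and MAPK targets into 2 and 4 among 18 (3 and 4 adjusted over the list alone), NF-kB and chemokine genes into 2 and 4 among 17 (4 and 7 adjusted over the list alone), p53 targets into 1 and 2 among 19 (3 and 3 adjusted over the list alone) and TGF-beta targets into 1 and 2 among 15, also adjusted over the list alone. Among 23 interferon-stimulated genes 1 fell over all genes and adjusted over the list alone (list adjusted p = 0.0816). Their list was called lower without the 3D library of SN3593 (adjusted p = 0.0205) or of SN3595 (adjusted p = 0.0231) or the 2D FNHCS library of SN3593 (adjusted p = 2.7e-07). Without the latter, the NF-kB list was called lower (adjusted p = 0.00024) and the ER and amino acid stress list higher (adjusted p = 1.14e-05, or adjusted p = 0.0332 without the filter). None of 15 ER stress genes (list adjusted p = 0.218) or 21 epithelial identity genes (list adjusted p = 0.816, median -0.11 and mean 0.11) was called by edgeR over all genes or adjusted over the list alone. At an unadjusted p below 0.05, 4 of each passed, while DESeq2 called 3 ER stress and 4 epithelial genes and limma-voom called 0. Of the other cell types, 1 airway gene rose and 1 fell, also adjusted over the list alone, 1 endothelial gene fell, also adjusted over the list alone, and 1 gastrointestinal gene each rose and fell adjusted over the list alone. None of the 4 fibroblast and 3 leukocyte genes tested was called by edgeR over all genes or adjusted over the list alone, and none had an unadjusted p below 0.05 or was called by DESeq2 or limma-voom. With line as a block, 3 epithelial identity, 2 TGF-beta and 2 p53 genes rose, and 1 epithelial identity, 3 interferon-stimulated, 2 ER stress, 2 airway and 1 gastrointestinal gene fell. Adjusted p for the 13 lists lay between 0.0816 and 0.962.

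The count of called genes in this comparison was 62 without the 2D FBS library of SN3593 (31 each way), 387 without that of SN3595 (278 higher, 109 lower), 482 without the 2D FNHCS library of SN3593 (239 higher, 243 lower), and 868 and 844 without the 3D library of SN3593 and SN3595 (475 and 467 higher, 393 and 377 lower), against 2700 with line as a block (1487 higher, 1213 lower), which kept 1527 of the 1531. Libraries did not overlap for 8614 genes (59.8%, chance 33.3%), and the split of 55.1% higher became 43.4% with upper-quartile factors (701 higher, 915 lower) and 29.8% with library size alone (625 higher, 1474 lower). It was 62.2% with limma-voom (821 higher, 498 lower) and 71.8% without the 2D FBS library of SN3595.

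**Figure D3:**
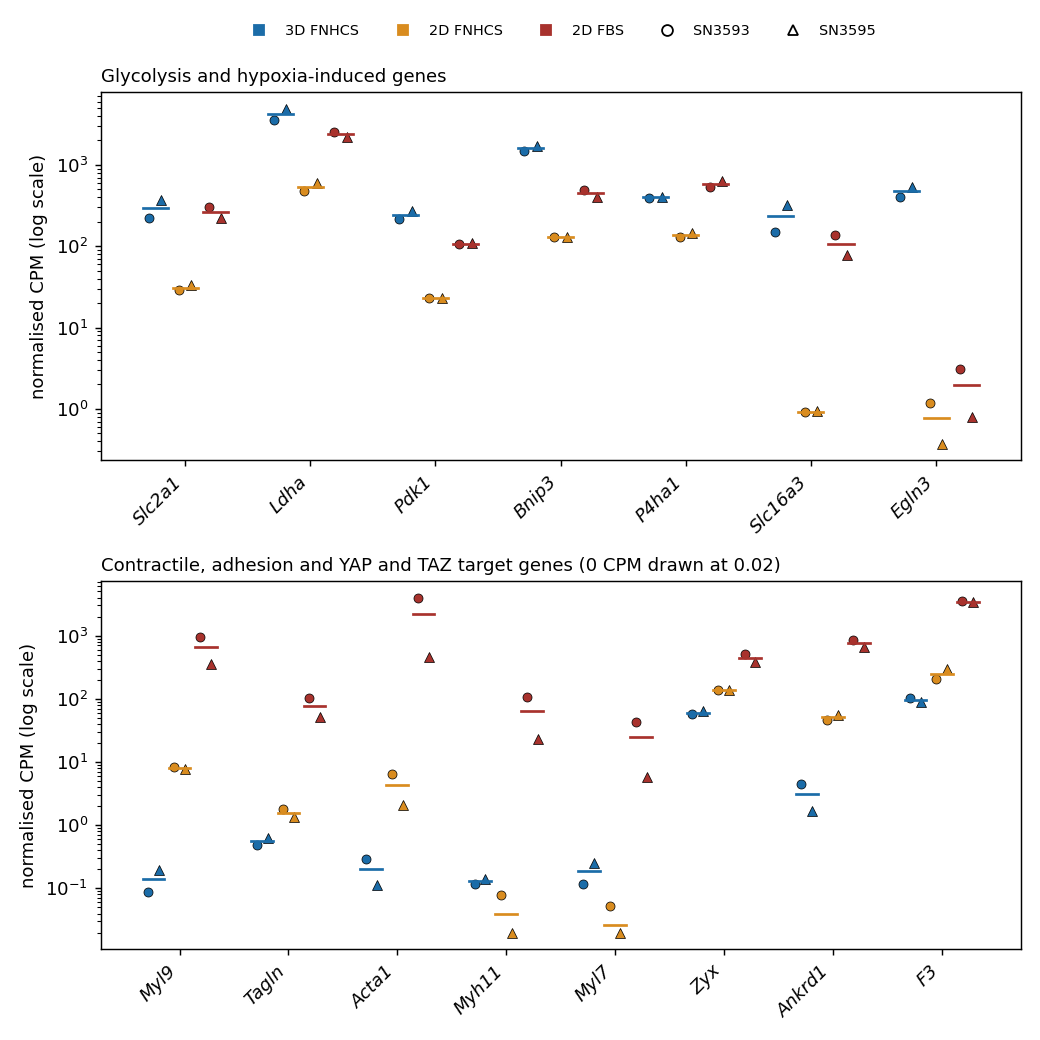
Normalised expression (CPM, log scale) per library of glycolysis and hypoxia-induced genes (top) and of contractile, adhesion and YAP and TAZ target genes (bottom), with colour for condition, symbol shape for line and a bar for the mean of 2 libraries; Slc2a1 and Ldha were chosen for the plot after their values were seen. Slc16a3 stood at 0.906 and 0.939 CPM in 2D FNHCS against 151 and 319 CPM in 3D FNHCS and 137 and 77.8 CPM in 2D FBS, and Myl9 stood at 945 and 357 CPM in 2D FBS.

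The third comparison joined both changes. Sftpc fell from 37260 ± 5312 to 351 ± 123 CPM (SD, n = 2; log2 fold change -6.73 ± 0.537 SE, adjusted p = 0.00106, edgeR), and Ager rose from 285 ± 58.5 to 8825 ± 1824 CPM (4.95 ± 0.534, adjusted p = 0.00175). Lamp3 fell by 11.03 ± 0.504 and Sftpa1 fell by 11.52 ± 0.604, while Igfbp2 rose by 10.75 ± 1.08 and Col4a3 by 5.65 ± 0.593. In all, 5836 of the genes tested (40.5%) were called, 2874 higher and 2962 lower in 2D FBS.

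Of 26 AT2 markers, 23 fell (24 adjusted over the list alone), with Lyz1 at -9.36 ± 0.447 and Sftpb at -8.46 ± 0.431. The list gave adjusted p = 6.88e-31, or adjusted p = 0.14 with an estimated correlation. Of 25 AT1 markers, 22 rose (24 adjusted over the list alone), with Col4a4 at 4.50 ± 0.634. Theirs gave adjusted p = 8.86e-10, or adjusted p = 0.387 with an estimated correlation. Hopx (2.39 ± 0.794, adjusted p = 0.0543), Pdpn (4.35 ± 1.63, adjusted p = 0.0768) and Nkx2-1 (-0.99 ± 0.359, adjusted p = 0.0705) were not called. All of them were called without the 2D FNHCS library of SN3593 (adjusted p = 0.0102, 0.0247 and 0.0214) or of SN3595 (adjusted p = 0.00988, 0.0266 and 0.0208), and Pdpn and Nkx2-1 with line as a block (adjusted p = 0.0071 and 0.0275). They were also called by DESeq2 (adjusted p = 0.00179, 0.00473 and 0.0364) and with only the 4 libraries compared in the fit (adjusted p = 0.0103, 0.0257 and 0.0208), Hopx without the filter (adjusted p = 0.0433), and Nkx2-1 with upper-quartile factors (adjusted p = 0.0332) or library size alone (adjusted p = 0.0382).

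The largest rises were those of the skeletal muscle actin gene Acta1, whose reads can be shared with other actins (13.39 ± 1.65, 3924 CPM in SN3593 and 461 CPM in SN3595 in 2D FBS), Col5a2 (at least 341-fold), the orphan receptor gene Gpr37 (at least 257-fold), Myl9 (12.12 ± 0.767) and Npy6r (at least 127-fold). The largest falls were those of the glycoprotein gene Lrg1 (at least 4000-fold lower), Npy2r (ratio 14800, counting interval 2650 to 583000, from 1 count in 2D FBS), the neutrophil chemokine gene Cxcl3 (ratio 5220, 1450 to 43100, from 2 counts), the kallikrein gene Klk13 (at least 125-fold lower) and Sftpa1.

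Of 25 actin cytoskeleton genes, 23 rose and 1 fell (24 and 1 adjusted over the list alone; list adjusted p = 3.42e-14, or adjusted p = 0.315 with an estimated correlation), with Tagln at 7.12 ± 0.473. Of 21 transitional state genes, 13 rose and 1 fell (15 and 2 adjusted over the list alone; list adjusted p = 6.5e-08, or adjusted p = 0.14 with an estimated correlation), with the calcium-binding protein gene S100a6 at 7.24 ± 0.416 and Plaur at 4.45 ± 0.213. Of 20 YAP and TAZ targets, 11 rose and 1 fell (12 and 1 adjusted over the list alone; list adjusted p = 1.53e-06, or adjusted p = 0.351 with an estimated correlation), with Ankrd1 at 7.93 ± 0.569 and F3 at 5.17 ± 0.314. Of 19 basement membrane and matrix genes, 13 rose (14 adjusted over the list alone; list adjusted p = 2.4e-06, or adjusted p = 0.315 with an estimated correlation), with Lox at 10.20 ± 1.02. Of 13 mesenchymal transition genes, 8 rose over all genes and adjusted over the list alone (list adjusted p = 0.000883, or adjusted p = 0.381 with an estimated correlation). The 13 tested include Acta2, also in the actin list, and Fn1 and Sparc, also in the matrix list. Of 19 p53 targets, 11 rose and 1 fell over all genes and adjusted over the list alone (list adjusted p = 0.0115, or adjusted p = 0.366 with an estimated correlation). Of 15 ER and amino acid stress genes, 8 rose over all genes and adjusted over the list alone (list adjusted p = 0.0196, or adjusted p = 0.42 with an estimated correlation).

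Of 29 cell cycle genes, 24 fell (25 adjusted over the list alone; list adjusted p = 4.53e-14, or adjusted p = 0.351 with an estimated correlation), with Cdk1 at -6.39 ± 0.287 and Cenpa at -5.89 ± 0.387. Of 20 fatty acid synthesis genes, 13 fell (14 adjusted over the list alone; list adjusted p = 2.32e-06, or adjusted p = 0.315 with an estimated correlation), with the desaturase gene Fads1 at -3.70 ± 0.303 and Gpam at -2.94 ± 0.249. Of 13 Wnt targets, 8 fell (9 adjusted over the list alone; list adjusted p = 6.5e-05, or adjusted p = 0.381 with an estimated correlation), with Sp5 at -2.36 ± 0.179 and the Wnt inhibitor gene Nkd1 at -4.50 ± 0.37. Of 14 immediate early genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone; list adjusted p = 8.61e-07, or adjusted p = 0.315 with an estimated correlation), with Fosb at -5.89 ± 0.327 and Socs3 at -3.39 ± 0.211. Of 12 BMP targets, 6 fell and 1 rose over all genes and adjusted over the list alone (list adjusted p = 0.00117, or adjusted p = 0.381 with an estimated correlation). Of 18 FGF and MAPK targets, 11 fell and 1 rose (11 and 2 adjusted over the list alone, 11 and 3 with line as a block; list adjusted p = 0.000883, or adjusted p = 0.285 with an estimated correlation). Of 17 NF-kB and chemokine genes, 10 fell and 4 rose (11 and 4 adjusted over the list alone; list adjusted p = 0.00625, or adjusted p = 0.53 with an estimated correlation). Of 7 MHC class II genes, 5 fell over all genes and adjusted over the list alone (list adjusted p = 0.00625, or adjusted p = 0.487 with an estimated correlation). Of 17 hypoxia and glycolysis genes, 9 fell (10 fell and 1 rose adjusted over the list alone; list adjusted p = 0.00388, or adjusted p = 0.449 with an estimated correlation), with a median of -1.03.

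The other 10 lists were not called. Epithelial identity genes split into 5 that rose and 4 that fell among 21, also adjusted over the list alone (8 and 6 with line as a block), TGF-beta targets into 4 and 5 among 15, also adjusted over the list alone, and cholesterol synthesis genes into 3 and 2 among 22, also adjusted over the list alone (7 and 4 with line as a block). Of 23 interferon-stimulated genes, 3 fell (1 adjusted over the list alone), and the list was called lower without the 3D library of SN3593 (adjusted p = 0.0111). All 3 mesothelial markers tested rose, also adjusted over the list alone, with list adjusted p = 0.0532, or adjusted p = 0.0442 with line as a block, 0.0372 with upper-quartile factors, 0.0419 with library size alone and 0.0141 without the filter. The mesothelial list was called without the 2D FNHCS library of SN3593 (adjusted p = 0.0236) or of SN3595 (adjusted p = 0.0246) and without the 2D FBS library of SN3593 (adjusted p = 0.0418) or of SN3595 (adjusted p = 0.00518). Among the other cell types, 2 airway, 1 gastrointestinal, 1 leukocyte and 1 endothelial gene rose, and 3 airway, 2 gastrointestinal, 1 leukocyte and 1 endothelial gene fell, with 5 airway genes that fell adjusted over the list alone and the rest as over all genes. None of 4 fibroblast genes was called by edgeR over all genes or adjusted over the list alone (1 at an unadjusted p below 0.05, 1 by DESeq2 and 1 by limma-voom). With line as a block, 2 interferon-stimulated and 1 fibroblast gene rose, and 5 airway and 1 fibroblast gene fell. Apart from the mesothelial list, adjusted p lay between 0.176 and 0.969.

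The count of called genes was 3281 and 3527 without the 3D library of SN3593 and SN3595, and 3550 and 3381 without the 2D FBS library of SN3593 and SN3595, with 1494, 1720, 1843 and 1775 higher and 1787, 1807, 1707 and 1606 lower in that order. The share that was higher was 49.2%, and became 40.8% with upper-quartile factors (2461 higher, 3577 lower) and 43.3% with library size alone (2598 higher, 3401 lower). Libraries did not overlap for 10812 genes (75%, chance 33.3%).

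The steps from 3D FNHCS to 2D FNHCS and on to 2D FBS were compared for shared genes. In both steps 188 genes rose, among them Igfbp2, Myl9, Ankrd1, Lox and Col5a2, where independent lists of these sizes would share 73. In both steps 219 fell, among them Lamp3, Sftpa1, Lyz1, Cebpa, Cdk1 and Cenpa, against 67. Genes that fell and then rose numbered 103, against 82, and included Pdk1, Bnip3, P4ha1 and Slc16a3. Genes that rose and then fell numbered 60, against 59. The values for independent lists give every gene the same chance of a call. Genes that are easier to call can raise each overlap without a shared response. With no effect simulated, each step called at most 1 gene in 20 runs, so the overlap of 0 in each run says nothing about sharing. The log2 fold changes of the steps had r = 0.15 across genes, which are not independent replicates, where the 2D FNHCS libraries they share gave r = -0.49 without an effect. The covariance was 0.26 against a simulated -0.14, a difference of 0.40, and steps taken from different lines, which share no library, had r = 0.17 and 0.23. The shared libraries alone would set the steps against each other, so part of the counts that moved in opposite directions may come from them. Without the 2D FBS library of SN3593 only 12 genes rose and 18 fell in both steps, and without that of SN3595 64 and 48. The counts were 60 and 78 without the 2D FNHCS library of SN3593, 103 and 96 without that of SN3595, 44 and 85 without the 3D library of SN3593, and 59 and 82 without that of SN3595. With line as a block they were 415 and 412. For genes that fell and then rose, leaving out a library in the same order gave 7, 48, 53, 88, 42 and 45, and for genes that rose and then fell it gave 5, 13, 25, 58, 12 and 18. With line as a block these were 204 and 179, and with library size scaling 75 and 190.

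The lines were compared across conditions with 3 libraries each. Gm19990, a predicted gene, was the only gene called, with 1555, 1093 and 187 counts in the 3D FNHCS, 2D FNHCS and 2D FBS libraries of SN3593 and 10163, 6883 and 1594 counts in those of SN3595 (log2 fold change 2.70 ± 0.133 SE, adjusted p = 0.0462, edgeR, higher in 3 of 3 conditions). It was named because it was the only call, after its values were seen. The noncoding RNA Xist of the inactive X chromosome had between 1201 and 8966 counts in the 6 libraries and did not differ detectably between lines (0.40 ± 0.165, adjusted p = 0.277). The Y-linked genes Eif2s3y and Kdm5d had 0 counts in each library, Ddx3y had at most 2 and Uty at most 11. At an unadjusted p below 0.05, 2678 genes (18.6%) passed, and DESeq2 called 748 (378 higher and 370 lower in SN3595). Without any 1 of the libraries edgeR called 0 genes, and Gm19990 had adjusted p between 0.094 and 0.206. It was also not called with upper-quartile factors (adjusted p = 0.0509), library size alone (adjusted p = 0.0566) or the stricter filter (adjusted p = 0.0713).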

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

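Of the tests in this part, the one for mixing between libraries was set out before its result was seen, and those for exchanged labels and for other splits of the libraries were chosen after the results were seen.

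AT1 markers stood further from their 3D level in the 2D FNHCS library of SN3595 than in that of SN3593. Of 25 markers, 24 were higher in SN3595, and the list median of the log2 changes was 0.60 in SN3593 and 2.84 in SN3595 from 3D FNHCS to 2D FNHCS, and 1.89 and 0.80 from 2D FNHCS to 2D FBS. The tables argue against 2D FBS cells or their RNA in the SN3595 library as the source of the whole difference. Compared were 16 other genes at 100 CPM or more in 2D FBS of SN3595 and at least 20 times above 2D FNHCS of SN3593. In 2D FNHCS of SN3595 they had covered a median of 3.8% of the way between these 2 levels (quartiles 1.4% and 13.9%). The AT1 markers had covered 45% (33.6% and 60.5%), the share that mixing would need. A smaller share of such cells or RNA was not excluded. The tables also argue against exchanged line labels within 2D FNHCS. In 3D FNHCS and 2D FBS, 350 genes differed at least 2-fold between the lines the same way. Of these, 312 (89.1%) differed that way in 2D FNHCS too. A difference between the lines in how far they had moved by day 7, or between these 2 cultures, stays open and untested, because each line has 1 library per condition.

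Hopx stood out because the lines moved in opposite directions from 3D FNHCS to 2D FNHCS, by -1.19 in SN3593 and by 2.33 in SN3595 on the log2 scale, a difference of 3.52 that was not tested. List medians also moved in opposite directions in the lines, and none of these differences was tested. From 3D FNHCS to 2D FNHCS, the TGF-beta targets moved by 0.13 in SN3593 and -0.73 in SN3595 (difference -0.86). Cholesterol synthesis genes moved by -0.65 and 0.18 over that step (difference 0.83). From 2D FNHCS to 2D FBS, the NF-kB and chemokine genes moved by 0.86 in SN3593 and -2.25 in SN3595 (difference -3.12). Epithelial identity genes moved by -0.14 and 0.10 over that step (difference 0.24), and gastrointestinal genes by -0.57 and 0.27 (difference 0.83). From 3D FNHCS to 2D FBS, the interferon-stimulated genes moved by 0.46 in SN3593 and -1.72 in SN3595 (difference -2.18).

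The comparison of lines was repeated for the 10 splits of the 6 libraries into 3 and 3, with condition kept as a term. Only 1 split, the real one, called as many as 1 gene with edgeR, and the highest of the others called 0 (in the real split 2678 genes passed an unadjusted p below 0.05, DESeq2 called 748 and limma-voom 1). Most of the other splits put both libraries of a condition on the same side. Their contrast then rests on a single condition, so their 0 calls are not comparable with the real split. With 10 splits the share cannot fall below 0.05.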

How the results depend on the processing

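All alternatives in this part were chosen before the data were examined. None of the genes called in a comparison of conditions was called in the opposite direction under any alternative. With 2 libraries per group, simulated 2-fold changes were recovered for 5.97%, 2.99% and 4.48% of the genes planted in the 3 comparisons. Those shares need not carry over to the data, where far more genes were called and the adjustment is less strict. Uncalled genes can still differ 2-fold. Where a library was left out, its condition kept 1 library, which was assumed to vary like the others. Such fits have fewer residual degrees of freedom. A call lost there can come from fewer libraries alone and need not mean that the result rested on the library left out.

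Counts of called genes in the first 2 comparisons of conditions moved most when a library was left out, and moved also with the tool, the block and the libraries in the fit. DESeq2 called 4210 genes in 2D FNHCS against 3D FNHCS and 3147 in 2D FBS against 2D FNHCS. With line as a block, which models the spread between lines, they were 4181 and 2700, and 415 genes rose and 412 fell in both steps. The block changed no call of a named gene or list besides those given with the results. With only the 4 libraries compared, 2D FBS against 2D FNHCS gave 828 genes. Leaving out 1 library gave 565 to 1869 genes in 2D FNHCS against 3D FNHCS, 62 to 1292 in 2D FBS against 2D FNHCS and 3281 to 6000 in 2D FBS against 3D FNHCS, with 12 to 103 genes that rose and 18 to 96 that fell in both steps. The remaining alternatives kept these counts within 1.5 times. Apart from fewer libraries, the cause was not tested.

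Between the lines, edgeR called 0 genes with upper-quartile factors, library size alone, the stricter filter, no group term or any 1 library left out, 73 without the filter, and 748 genes were called by DESeq2 (2678 passed an unadjusted p below 0.05, and limma-voom called 1).

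List tests depended on the inter-gene correlation. Camera called 17, 14 and 18 lists in the 3 comparisons at the preset value and 0 in each with an estimated correlation, while fry called 8, 7 and 19. With an estimated correlation, adjusted p for the AT2 markers was 0.219, 0.0965 and 0.14, and for the AT1 markers 0.519, 0.625 and 0.387. The estimates were 0.12, 0.13 and 0.17 for the AT2 list and 0.83, 0.74 and 0.81 for the AT1 list, against the preset 0.01. By fry, the AT1 markers had adjusted p = 0.168 and 0.244 in the first and second comparison. Both lists were called by camera with the other scalings and filters, with line as a block and with each library left out, and the AT2 list by fry in all 3 comparisons. In the first comparison fry also did not call the YAP and TAZ, actin, matrix, mesenchymal, Wnt, cell cycle, NF-kB, p53 and ER stress lists. In the second it did not call the YAP and TAZ, matrix, mesenchymal, Wnt, fatty acid, cholesterol and MHC class II lists. In the third it did not call the NF-kB and MHC class II lists. Camera had called them all at the preset correlation. List tests were not run with DESeq2, limma-voom, only the 4 libraries compared or a 2-fold minimum. Of the lists that camera did not call, fry called the endothelial list lower in the 3 comparisons (adjusted p = 0.0365, 0.00515 and 0.00238) and, in 2D FBS against 3D FNHCS, the epithelial identity and mesothelial lists higher (adjusted p = 0.038 and 0.0166). Only 2 endothelial genes were tested, and in 2D FBS against 3D FNHCS 1 rose and 1 fell, so these calls do not show a shared fall. The interferon list in 2D FNHCS against 3D FNHCS turned from higher (adjusted p = 0.863) to lower (adjusted p = 0.0116) without the 2D FNHCS library of SN3595, where the range over left-out libraries reached 0.905, and the cause was not tested. With the stricter filter the mesothelial list had too few genes and was not tested.

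Scaling turned the sign of some small list medians. In 2D FNHCS against 3D FNHCS, upper-quartile factors moved the interferon list from 0.04 to -0.03 and the endothelial list from 0.02 to -0.01. In 2D FBS against 2D FNHCS, RLE factors moved the BMP list from -0.01 to 0.01, and library size alone moved the p53 list from 0.25 to -0.04. The endothelial median in 2D FNHCS against 3D FNHCS lay above 0 while the list test pointed down, and the leukocyte list in 2D FBS against 3D FNHCS had a median of -0.15, a mean of 1.13 and a test pointing down.

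Of the named genes, 37, 36 and 35 in the 3 comparisons, none changed its call with RLE factors, the stricter filter or a 2-fold minimum. DESeq2 changed 0, 2 and 3 of them and limma-voom 1, 4 and 0. With only the 4 libraries compared, Saa3, Spock2, Timp3 and Pmvk lost their calls in 2D FBS against 2D FNHCS (adjusted p = 0.0584, 0.0557, 0.0596 and 0.054). Counts of called list members moved with the tool too: in 2D FNHCS against 3D FNHCS 7 AT1 markers became 16 with DESeq2, and in 2D FBS against 2D FNHCS 6 NF-kB and chemokine genes became 2 with limma-voom. Without the 2D FBS library of SN3593, 19 of the named genes lost their call in 2D FBS against 2D FNHCS.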

Other observations

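The genes named in the first 2 paragraphs of this part were chosen after their values were seen, and all tests in this part were chosen after the results were seen. The hypoxia and glycolysis genes did not move as a unit in the second step. The glucose transporter gene Slc2a1 fell from 3D FNHCS to 2D FNHCS (-3.25 ± 0.317 SE, adjusted p = 0.00462, edgeR) and rose from 2D FNHCS to 2D FBS (3.08 ± 0.315, adjusted p = 0.00902), with 301 and 223 CPM in the 2D FBS libraries of SN3593 and SN3595 against 224 and 367 CPM in 3D FNHCS. Egln3 and the vasodilator peptide gene Adm fell in the first step and stood low in 2D FBS too, at 3.13 and 0.785 CPM for Egln3 and 3.97 and 1.27 CPM for Adm, against 404 and 543 CPM and 68.8 and 73.0 CPM in 3D FNHCS. Calls in this and the next paragraph were not lost with line as a block, but the Slc2a1 call in 2D FBS against 2D FNHCS was lost without the 2D FBS library of SN3593 (adjusted p = 0.0603).

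Other groups split within themselves. Among BMP targets, Id1, Id2 and Id3 all fell from 3D FNHCS to 2D FNHCS (-4.00, -4.35 and -3.04), then Id1 and Id3 rose in 2D FBS (1.85 and 2.68) while Id2 fell further (-2.54). Nog, which encodes the BMP antagonist noggin, rose in each step (4.40 ± 0.366 and 1.74 ± 0.304). Among inflammatory genes, Csf3 and the cyclooxygenase gene Ptgs2 rose in 2D FBS (7.71 ± 1.1 and 3.90 ± 0.553, adjusted p = 0.016 for each), while Csf2 and the chemokine gene Cxcl2 fell (-6.94 ± 0.622 and -2.50 ± 0.529). Etv5, an FGF-induced transcription factor gene that AT2 cells express, fell in both steps (-2.00 ± 0.355 and -4.04 ± 0.389), and the simple epithelial keratin gene Krt7 rose in both (1.84 ± 0.39 and 2.23 ± 0.396). In 2D FNHCS the MHC class II gene H2-Ab1 stood at 476 CPM in SN3593 and 103 CPM in SN3595, and the interferon-stimulated gene Isg15 at 1.37 and 20.4 CPM. Of the 11 calls in 2D FBS against 2D FNHCS in these 2 paragraphs, 10 were lost without the 2D FBS library of SN3593 (adjusted p between 0.0531 and 0.132), and that of Csf2 was not. Without the 2D FBS library of SN3595, calls were lost for Nog, Ptgs2, Cxcl2 and Krt7 (adjusted p = 0.105, 0.0511, 0.17 and 0.0808), and without the 2D FNHCS library of SN3593 for Nog, Csf3, Ptgs2 and Krt7 (adjusted p = 0.0807, 0.0585, 0.0538 and 0.0874). Cxcl2 was not called either without the 2D FNHCS library of SN3595 (adjusted p = 0.0734) or the 3D library of SN3593 or SN3595 (adjusted p = 0.051 and 0.0538), or with only the 4 libraries compared (adjusted p = 0.0638). By limma-voom, Csf3 and Cxcl2 had adjusted p = 0.0548 and 0.106. In 2D FNHCS against 3D FNHCS, Etv5 and Krt7 were not called without the 3D library of SN3593 (adjusted p = 0.0728 and 0.0637) or of SN3595 (adjusted p = 0.0627 and 0.109). In that comparison Krt7 also lost its call without the 2D FNHCS library of SN3595 (adjusted p = 0.0804) or the 2D FBS library of SN3593 or SN3595 (adjusted p = 0.0535 and 0.0546).

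The hypoxia and glycolysis list was lower in 2D FNHCS than in 3D FNHCS and 2D FBS at the preset correlation (adjusted p = 0.219 and adjusted p = 0.318 with an estimated correlation). Normalization between libraries was argued against, since over 4 ways of scaling the list median nearest 0 was -2.80 in 2D FNHCS against 3D FNHCS and 1.60 in 2D FBS against 2D FNHCS. Handling before lysis, as marked by immediate early genes, cannot be told apart in either step. In the second step the 14 immediate early genes did not rise with the list, with a median of -0.37 (SD 1.25) against 1.88. The medium changed in that step too and may act on these genes, so their median cannot decide. In the first step the immediate early genes fell too, with a median of -1.74 (SD 1.60) against -2.96 for the list. A hypothesis that stays open and untested is that oxygen or nutrient supply or cell density differed between the conditions, or in the second step the medium, which may set these genes.

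Contractile genes were higher in 2D FBS, with medians of 838 CPM in SN3593 and 137 CPM in SN3595 over 7 genes that were grouped after their values were seen, 4 of them from the actin cytoskeleton list. The tables argue against fibroblasts among the cells, since 12 abundant fibroblast transcripts (2 at 1 CPM or more in 3D FNHCS) had a median of at most 0.115 CPM in either 2D FBS library, with Col1a1 at 0.345 and 0.127 CPM and 1 called higher (Pcolce). Values of 5 pericyte genes (2 at 1 CPM or more in 3D FNHCS) argue against pericytes too. Their median was at most 0.43 CPM in either 2D FBS library, with Pdgfrb at 0 and 0.0506 CPM. Mcam stood at 2360 and 1920 CPM, though at 1730 and 1700 CPM already in 2D FNHCS. The endosialin gene Cd248, which pericytes and fibroblasts can also express, was in neither set. It rose from 2D FNHCS to 2D FBS (9.89 ± 0.735, from 1 count), so both readings cover only the genes in these sets. Smooth muscle cells cannot be told apart. Their 7 genes (2 at 1 CPM or more in 3D FNHCS) had medians of 8.65 and 1.42 CPM in 2D FBS. Of the 7, 2 were called higher in 2D FBS than in 2D FNHCS. Lmod1 rose from 0.259 and 0.164 to 40.1 and 6.84 CPM. Hspb6 rose from 2.36 and 1.76 to 60.2 and 11.7 CPM, while Des stood at 0.172 and 0 CPM. Mesothelial cells were not examined as a source of these genes, though their markers also rose in 2D FBS. Of 3 tested, 1 was called higher than in 2D FNHCS and 3 higher than in 3D FNHCS. Their list gave adjusted p = 0.0222 and 0.0532 with camera in that order, or adjusted p = 0.378 and 0.366 with an estimated correlation. A contractile programme of the epithelial cells in serum medium is a hypothesis that stays open as well, found and examined on the same data.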
